A study of Homo sapiens with 12 samples.

How the data were processed

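Gene expression was measured in 12 pieces of human endocervix, the mucus-secreting canal of the cervix, taken from hysterectomy specimens. Per the labels' protocols, total RNA was isolated with a fibrous tissue kit from Qiagen, checked on an Agilent Bioanalyser, and turned into biotinylated cRNA with the Ambion MessageAmp kit for Illumina bead arrays. Endometrial dating, per the series' design text, put 8 specimens in the follicular phase of the menstrual cycle and 4 in the luteal phase. Every specimen was hybridized to its own array. The labels do not state whether each piece came from a separate donor, so the p-values measure the spread between these samples. Samples were numbered within each phase in accession order, which pairs no samples.

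The authors deposited, for each of 47323 probes and each array, the intensity of the probe on a linear scale, not normalized between arrays. Beside it stands a detection p-value, per the file headers, which in the values ran in steps of 1 in 770. The authors also deposited a matrix of log2 values. All 12 of its columns had a median of 6.93 and identical quantiles, so these values had been quantile-normalized. Within each array they ranked the probes as the intensities did, with a Spearman correlation of 1, so no background correction that reorders probes was visible. The scanner software and the normalization tool are not given in the sources used here. The scale of the matrix was read from its values.

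Background was corrected and arrays were normalized from the intensities with neqc in limma 3.58.1 under R 4.3.3, which estimates the background from the detection p-values, adds an offset of 16, quantile-normalizes and takes log2. An offset shrinks the differences of dim probes. A probe was kept where its detection p was under 0.05 in at least 4 of the 12 arrays, which left 22445 probes. Probes were named from the platform's annotation: 30113 had 1 gene symbol, 8 had several and were not named, and 17202 had none listed there. Of the named probes, 30074 took a current symbol through their Entrez gene number. A gene was represented by its kept probe with the highest mean over all arrays, which gave 13217 genes. Differences of other detected probes of a named gene are given beside it where they disagree.

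Luteal minus follicular differences were fitted with lmFit and eBayes with an intensity trend, over all 12 arrays and with no covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Tests were two-sided. The number of arrays limits the precision. On data simulated for this comparison of 4 against 8 arrays over 13217 genes, the procedure called 3 of 50 genes changed by 0.5 on the log2 scale, 17 of 50 changed by 1, 27 of 50 changed by 1.5 and 49 of 50 changed by 2, with 5 false calls. The simulated noise was normal, independent between genes and without an outlying array, so these rates may not carry over to the real arrays.

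A set of 34 gene lists was fixed before the data were examined, covering the cell types a piece of endocervix can hold, hormone response, mucus, immunity, stress and tissue remodelling. Of their 526 entries, 430 were measured. Lists were tested with limma's camera at a preset correlation of 0.01 between genes and adjusted over the lists. They were tested again with a correlation estimated from the data. An exact permutation test of each list's mean per array, over all splits of the arrays into 8 and 4, was added after the data had been seen. Its smallest possible p was 0.0020, too large for a list to pass alone after adjustment over the 34 lists.

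Genes are named by a rule fixed beforehand. It takes the 12 called genes of largest difference in each direction, filled up with the genes of smallest p, which are then described by their values only. In each list described it takes up to 4 called members, or else the 2 members of smallest p, and it adds the receptors ESR1 and PGR. A further item of the rule is not reported here. Genes on the sex chromosomes that mark sex, genes whose level follows common deletions or haplotypes, and unnamed loci were left out of naming. Where a probe was detected in no array of a group, its difference is a bound, taken against the lowest detected signal.

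Alternatives planned beforehand covered the background correction, the authors' matrix, the detection filter, the choice of probe, the variance model (eBayes without trend, or robust, with statmod 1.5.0), array weights, the threshold, the means of smooth muscle, squamous or columnar genes as covariates, the correlation in camera, and leaving out each array in turn. A setting without probes whose gene has another probe detected on no array was added after the data had been seen. A slide or scan block was planned, but the files used here name no slide or scan. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.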

Results

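Whole endocervical tissue from 8 follicular-phase and 4 luteal-phase specimens was profiled on bead arrays. The follicular phase precedes ovulation and is dominated by estradiol, and the luteal phase follows it, with high progesterone. The follicular arrays detected 20622 ± 1235 probes (SD, n = 8; range 17706 to 21674) and the luteal arrays 20205 ± 566 (SD, n = 4; range 19578 to 20858), which did not differ (exact permutation p = 0.60, two-sided). The median unnormalized signal was 103 ± 4.38 in the follicular arrays (SD, n = 8) and 98.2 ± 2.35 in the luteal arrays (SD, n = 4), with an exact permutation p of 0.0747. Spearman correlations between pairs of arrays ran from 0.689 to 0.968.

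The study asked which transcripts of the endocervix differ between the phases of the cycle. Cell division genes lay lower in luteal tissue, and genes of ciliated cells and immediate-early genes lay higher, when tested as groups. Genes of mast cells, estrogen-induced genes and genes of fibroblasts and stroma also lay lower, and genes of antigen presentation on MHC class II, complement and columnar epithelium lay higher. These are the 9 of 34 lists past the threshold with camera. None of them passed with a correlation estimated from the data (smallest adjusted p = 0.697) or in the exact permutation test of list means (smallest adjusted p = 0.687). A list could not pass that permutation test alone, even at the smallest possible p, so a miss there says little about any single list. Camera used a preset correlation of 0.01, while the data gave 0.45 for proliferation, 0.81 for ciliated cells and 0.38 for immediate-early genes. Other splits of the arrays into groups of the same sizes gave a median of 10 lists in camera, against 9 here. At least 9 were called in 67 of 100 splits, so the number of lists does not set the phases apart from chance. No single gene of the 13217 tested passed an adjusted p of 0.05 in limma. At an unadjusted p under 0.05 there were 701 genes, 308 higher and 393 lower in the luteal phase, where chance alone gives 661.

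Proliferation genes had the smallest list p. Of 14 measured members, 13 were lower in the luteal phase, with a mean difference of -0.68 on the log2 scale and an adjusted p of 9.6e-08 in camera. With an estimated correlation the camera p was 0.0369 before adjustment, the only 1 of 34 lists under 0.05 there. After adjustment it was 0.697, a value that several lists share. The exact permutation p of the list mean was 0.0202 before adjustment. All 4 luteal arrays, from 5.04 to 5.18, lay below 7 of the 8 follicular arrays. TOP2A, the topoisomerase that untangles DNA at mitosis, averaged 6.14 ± 1.0 (SD, n = 8) in follicular and 4.44 ± 0.20 (SD, n = 4) in luteal tissue, where 1 of 4 arrays detected it. Its difference was -1.70 ± 0.47 (SE), and -0.56 with the authors' values. TYMS, which makes thymidylate for DNA synthesis, differed by -1.09 ± 0.33 (SE), and by -0.46 with the authors' values. Adjusted over the list alone, 4 members passed, against 0 over all genes: TOP2A, TYMS, UBE2C at -1.53 and CCNB1 at -0.53. The last pair was named after its values were seen, and 1 of 4 luteal arrays detected UBE2C and 2 of 4 CCNB1, so their luteal levels lie near background. With the authors' values the list's mean difference was -0.22 and it stayed past the threshold.

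All 13 measured genes of ciliated cells were higher in the luteal phase, with a mean difference of 0.88 and an adjusted p of 3.2e-06 in camera. The adjusted p was 0.697 with an estimated correlation. ROPN1L, a protein of the axoneme and sperm tail, differed by 1.29 ± 0.60 (SE), and ZMYND10, needed to assemble dynein arms, by 0.87 ± 0.44 (SE). With the authors' values they differed by 0.56 and 0.28, and without luteal replicate 4 by 0.75 and 0.39. No member passed when adjusted over the list alone. The luteal arrays spread from 5.74 to 8.30 and the follicular arrays from 4.78 to 7.63, so the groups overlapped. Luteal replicates 4 and 3 and follicular replicate 6 were highest for this list, at 8.30, 6.89 and 7.63. The same arrays were highest for columnar epithelium genes, at 10.54, 10.63 and 10.38. Without luteal replicate 4, the array at 8.30, the mean difference was 0.41 with an adjusted p of 0.0415. It was 0.42 with the authors' values, 0.52 with the smooth muscle mean as a covariate and 0.65 with the columnar epithelium mean as a covariate, past the threshold in each.

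Immediate-early genes, which respond within minutes to growth factors or stress, were higher in the luteal phase for 15 of 16 members. Their mean difference was 0.61, with an adjusted p of 1.5e-04 in camera and 0.697 with an estimated correlation. ATF3 averaged 9.55 ± 0.64 (SD, n = 8) in follicular and 10.83 ± 0.73 (SD, n = 4) in luteal tissue, a difference of 1.28. A dimmer ATF3 probe, detected in 3 arrays, differed by 0.58. NR4A3, an orphan nuclear receptor, differed by 1.04 on its brightest probe, or 0.34 with the authors' values, while another 2 of its probes, detected in at most 1 array, differed by -0.02 and -0.0031. On the brightest probe its difference ran from 0.57 to 1.37 with single arrays left out. No member passed when adjusted over the list alone. Without follicular replicate 2, in which the list averaged 8.24 against 9.93 ± 0.50 in the other 7 follicular arrays (SD, n = 7), the mean difference was 0.40 with an adjusted p of 0.0388. With array weights it was 0.37.

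Genes of antigen presentation on MHC class II were higher for all 9 measured members, by 0.47 on average, with an adjusted p of 0.0025 in camera and 0.697 with an estimated correlation. The protease CTSS differed by 0.52 ± 0.22 (SE) and HLA-DPB1 by 0.96 ± 0.44 (SE). With the authors' values these were 0.13 and 0.38, and the list mean 0.28. Complement genes were higher for 13 of 15 members, by 0.41 on average, with an adjusted p of 0.0333 in camera and 0.697 with an estimated correlation. The C1 inhibitor SERPING1 differed by 1.05 ± 0.40 (SE) and C5 by 0.39 ± 0.29 (SE). C5 differed by 0.18 and the list by 0.27 with the authors' values. With single arrays left out C5 ran from 0.20 to 0.51. A dimmer SERPING1 probe, detected in 2 arrays, differed by 0.0037. No member of either list passed when adjusted over its list alone. Without follicular replicate 2, in which epithelial genes were near background, neither list passed, with mean differences of 0.34 and 0.16 and adjusted p-values of 0.126 and 0.406. The complement list also missed the threshold without luteal replicate 2, where its difference was no smaller (0.43, adjusted p = 0.0535), without luteal replicate 4 (0.25, adjusted p = 0.257), and with the smooth muscle (0.23, adjusted p = 0.153) or columnar epithelium mean (0.17, adjusted p = 0.316) as a covariate. MHC class II missed it with the columnar mean as a covariate (0.30, adjusted p = 0.125). Both missed it with array weights, MHC class II at 0.27 and complement at 0.19. With detection in all 12 arrays they missed it at 0.37 and 0.49 (adjusted p = 0.119 and 0.0580).

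Mast cell genes were lower for all 6 measured members, by -0.89 on average, with an adjusted p of 0.0025 in camera and 0.697 with an estimated correlation. The tryptases TPSB2 and TPSAB1 differed by -1.38 ± 0.49 (SE) and -1.29 ± 0.47 (SE). They are near-identical paralogs whose probes may not separate them. The list was lowest in luteal replicates 3 and 4 and follicular replicate 6, at 6.07, 6.16 and 6.58. The same 3 arrays were lowest for endothelial genes, at 5.995, 6.09 and 5.86, and with follicular replicate 2 (9.70) they were lowest for fibroblasts and stroma, at 9.72, 9.97 and 9.51. No member passed when adjusted over the list alone, and the list did not pass without luteal replicate 3 (-0.58, adjusted p = 0.161) or with the columnar epithelium mean as a covariate (-0.78, adjusted p = 0.0635). With the authors' values the mean difference was -0.55, and that of TPSB2 -0.89.

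Estrogen-induced genes were lower in the luteal phase for 12 of 15 members, by -0.41 on average, with an adjusted p of 0.0349 in camera and 0.697 with an estimated correlation. IGFBP4, which binds insulin-like growth factors, averaged 11.96 ± 0.52 (SD, n = 8) in follicular and 10.997 ± 0.12 (SD, n = 4) in luteal tissue, a difference of -0.96. It was the 1 member past the threshold when adjusted over the list alone. IGF1 differed by -1.74 ± 0.73 (SE), and by -0.93 on a dimmer probe detected in 7 arrays. It differed by -1.01 with the authors' values. Some arrays were extreme for both this list and stroma genes: follicular replicates 3 and 5 were highest for both (8.54 and 8.35, stroma 12.18 and 12.28). Luteal replicates 3 and 4 were lowest for the estrogen-induced genes, at 7.62 and 7.32, and low for stroma, at 9.72 and 9.97. Follicular replicate 7 did not follow this, low for the estrogen-induced genes at 7.67 and high for stroma at 11.62. The list did not pass without luteal replicate 3 (-0.41, adjusted p = 0.0597) or with array weights (-0.45, adjusted p = 0.0550), where the difference was no smaller, or without luteal replicate 4 (-0.31, adjusted p = 0.187). Nor did it pass with the smooth muscle (-0.36, adjusted p = 0.0504) or columnar epithelium mean (-0.43, adjusted p = 0.0635) as a covariate. The receptors themselves showed small differences: ESR1, the main estrogen receptor, differed by -0.14 ± 0.33 (SE) and PGR, the progesterone receptor, by -0.32 ± 0.32 (SE), or -0.21 with the authors' values. PGR ran from -0.53 to -0.17 with single arrays left out.

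Genes of fibroblasts and stroma were lower for 7 of 12 members and higher for 5, with a mean difference of -0.64, an adjusted p of 0.0349 in camera and 0.932 with an estimated correlation. The lower members of smallest p were fibrillar collagens. COL3A1 differed by -1.47 ± 0.56 (SE) and COL5A1 by -1.70 ± 0.65 (SE), and no member passed when adjusted over the list alone. This call was lost without any of 7 single arrays, namely follicular replicates 3, 4, 5, 7 and 8 and luteal replicates 3 and 4. The difference was -0.61, -0.58 and -0.62 without follicular replicates 4, 7 and 8 (adjusted p = 0.0550 to 0.0839), near the -0.64 over all arrays. It was -0.50 and -0.48 without follicular replicates 3 and 5, and -0.38 and -0.46 without luteal replicates 3 and 4. The call was also lost with the smooth muscle (-0.49, adjusted p = 0.0504) or columnar epithelium mean (-0.74, adjusted p = 0.0635) as a covariate, with every probe tested (-0.40), and without bright probes whose gene has another probe detected on no array (-0.56).

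Columnar epithelium genes were higher for 16 of 19 members, by 0.66 on average, with an adjusted p of 0.0349 in camera and 0.932 with an estimated correlation. CLDN3, a tight junction protein, differed by 1.44 ± 0.71 (SE) and the mucin MUC4 by 1.46 ± 1.10 (SE), and no member passed when adjusted over the list alone. Another 3 MUC4 probes, each detected in at most 3 arrays, differed by 0.30, 0.16 and 0.0024. MUC4 differed by 0.65 and the list by 0.40 with the authors' values. The difference rested on follicular replicate 2, where the list averaged 4.80 against 9.89 ± 0.46 in the other 7 follicular arrays (SD, n = 7). Without that array the mean difference was 0.02 and the adjusted p 0.970. The list also missed the threshold without follicular replicate 5 (0.64, adjusted p = 0.0554), luteal replicate 3 (0.42) or luteal replicate 4 (0.45), with every probe tested (0.59), with array weights (0.12) and with the smooth muscle mean as a covariate (0.13, adjusted p = 0.716).

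**Figure D1:**
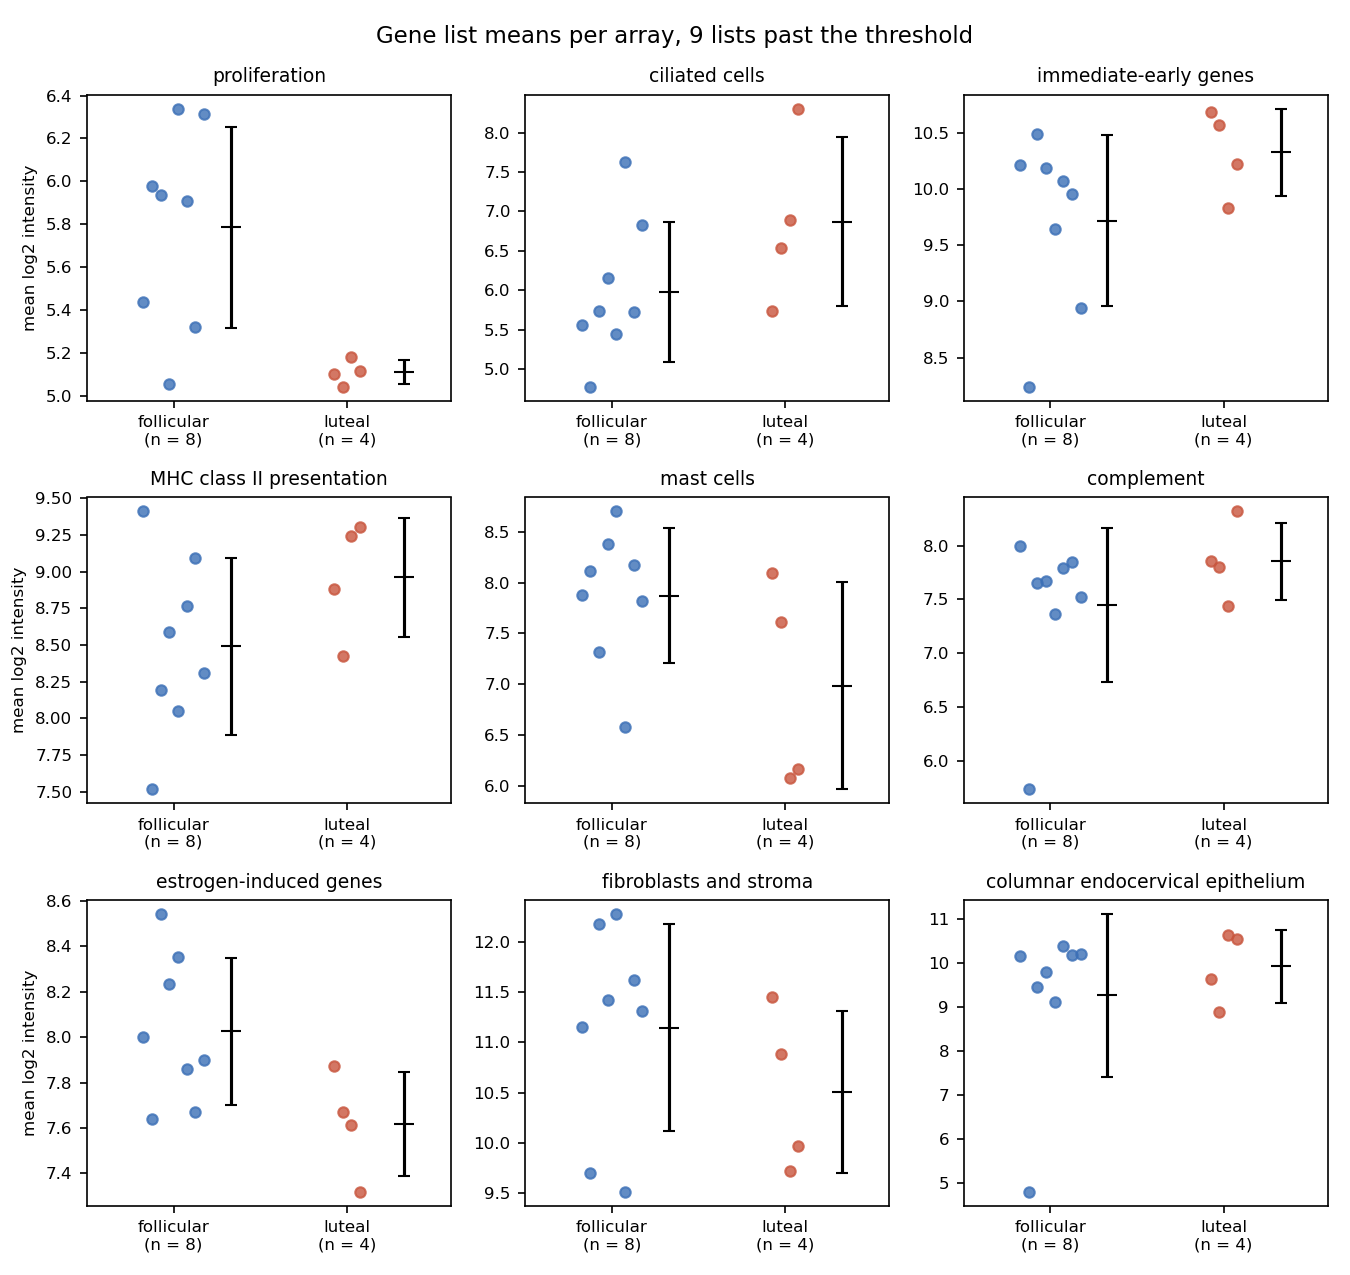
Mean log2 intensity of each of the 9 lists past the threshold with camera, per array (dots, follicular n = 8 in blue, luteal n = 4 in red), with the group mean ± SD in black; vertical axes differ between panels. The 4 luteal arrays sit between 5.04 and 5.18 for proliferation genes, below 7 of 8 follicular arrays, and follicular replicate 2 is the lowest dot for columnar epithelium at 4.80.

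The remaining 25 lists did not pass in camera. Hypoxia response genes came nearest, with a mean difference of 0.28 and an adjusted p of 0.0539, followed by smooth muscle genes at -0.65 (adjusted p = 0.103), of which 10 of 11 were lower. Hypoxia response passed in 12 of 28 alternatives, with adjusted p-values from 0.0043 to 0.780, and smooth muscle in 5 of 27, from 8.0e-04 to 0.932. The 12 include the looser threshold of 0.10, which hypoxia response passed at the same adjusted p of 0.0539. Leaving out single arrays gave smooth muscle differences from -1.23 to -0.33, the last without follicular replicate 2, and 0.18 for hypoxia response without that array. Genes of secretory-phase endometrium differed by 0.26 (adjusted p = 0.201) and mucins and their partners by 0.45 (adjusted p = 0.220). Without follicular replicate 2 these were 0.02 (adjusted p = 0.777) and 0.09 (adjusted p = 0.928). Progestin- and glucocorticoid-induced genes, 15 of 18 of them higher, differed by 0.14, heat shock proteins by 0.26 and endothelial genes by -0.16, each with an adjusted p of 0.261. The progestin and glucocorticoid list ran from 0.035 to 0.21 with single arrays left out. Red blood cell genes differed by -0.29 (adjusted p = 0.296) and squamous epithelium genes by -0.60 (adjusted p = 0.364), with follicular arrays from 4.55 to 11.7.

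Among leukocyte lists, monocyte and macrophage genes differed by 0.06 (adjusted p = 0.364), dendritic cell genes by -0.09 (adjusted p = 0.390) and neutrophil genes by -0.22 (adjusted p = 0.50). With single arrays left out, dendritic cell genes ran from -0.20 to -0.018 and neutrophil genes from -0.47 to -0.0051. T cell genes differed by -0.0024 (adjusted p = 0.832), genes of NK and cytotoxic cells by -0.09 (adjusted p = 0.847) and genes of B and plasma cells by -0.04 (adjusted p = 0.947). HIV receptors and restriction factors differed by -0.08 (adjusted p = 0.390). Interferon-stimulated genes differed by 0.05 (adjusted p = 0.661), and IRF7 alone passed when adjusted over that list. Inflammatory cytokines and NF-kB targets differed by 0.0014 (adjusted p = 0.707) and antimicrobial proteins by -0.10 (adjusted p = 0.985).

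Epithelial junction genes differed by 0.21 (adjusted p = 0.412), matrix remodelling genes by -0.07 (adjusted p = 0.655), and ion and water transport genes by -0.05 and prostaglandin metabolism genes by -0.06 (adjusted p = 0.832 for each). Steroid receptors and coregulators differed by -0.11 (adjusted p = 0.844) and ribosomal proteins by -0.02 (adjusted p = 0.354). For 3 lists the signs of mean, median and test differed. Ribosomal proteins had a median of 0.07 and inflammatory genes one of -0.02, against means of -0.02 and 0.0014. Camera ranked both lists and the B and plasma cell list as higher, the last with a median of -0.05.

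None of the single genes passed the adjusted threshold, and those of smallest p are given by their values. APOC1, an apolipoprotein of lipid-carrying particles, had the smallest p (adjusted p = 0.571 in limma). It averaged 5.96 ± 0.46 (SD, n = 8) in follicular and 7.93 ± 0.75 (SD, n = 4) in luteal tissue, 3.92-fold higher. Its difference of 1.97 on the log2 scale was 1.05 with the authors' values and 1.11 with no background correction. IRF7, a transcription factor of the interferon response, was 2.13-fold higher (adjusted p = 0.608), with 1.09 on the log2 scale, 0.61 with the authors' values and 0.59 on a dimmer probe. The secreted ribonuclease ANG was 2.53-fold higher (adjusted p = 0.775), with 1.45 on the log2 scale on another probe. MYBPC1, a myosin-binding protein of muscle, averaged 4.59 ± 0.22 (SD, n = 8) in follicular and 6.58 ± 1.20 (SD, n = 4) in luteal tissue (adjusted p = 0.608), with 0.9998 on the log2 scale on a dimmer probe detected in 3 arrays. Without luteal replicate 4, where it lay at 4.80, the difference was 2.61 with an adjusted p of 6.7e-05. Over all arrays it was 1.99, or 0.71 with the authors' values and 0.77 with no background correction.

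The other higher genes of smallest p each had an adjusted p of 0.905. They were the peptidase DPP7 at 1.16 on the log2 scale, the bicarbonate transporter SLC4A7 at 0.97, JADE1 at 0.87, the sterol hydroxylase CYP27A1 at 0.85, ABTB1 at 0.84, RSPH9 of the ciliary radial spoke at 0.70, CDHR1 at 0.69 and the delta opioid receptor OPRD1 at 0.56. Further probes of SLC4A7 and JADE1 that were detected in at least 11 arrays differed by 0.13 and 0.05, and further DPP7 probes by 0.25 to 0.65. JADE1 differed by 0.53, RSPH9 and CDHR1 by 0.17 each and OPRD1 by 0.13 with the authors' values.

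The 12 lower genes of smallest p also each had an adjusted p of 0.905. CLEC11A, a secreted growth factor, differed by -1.47 ± 0.40 (SE), and IGFBP4 is given with the estrogen-induced genes. RACGAP1, needed for cytokinesis, differed by -0.92 ± 0.23 (SE), PARPBP by -0.85 ± 0.22 (SE) and MASTL, a kinase of mitotic entry, by -0.72 ± 0.19 (SE). Further RACGAP1, PARPBP and MASTL probes differed by -0.25, -0.05 and -0.24, and with the authors' values the 3 genes differed by -0.26, -0.22 and -0.18. The RNA-binding protein SYNCRIP differed by -0.83, FKBP1A by -0.82, the glutamate transporter SLC1A1 by -0.80, ZDHHC24 by -0.74, the DNA repair endonuclease APEX1 by -0.63 and the aminopeptidase XPNPEP1 by -0.51. Further probes differed by -0.07 for APEX1 and by -0.0093 to -0.69 for FKBP1A. SLC1A1 and ZDHHC24 differed by -0.21 each with the authors' values. LINC00863, a noncoding RNA, was detected in 7 of 8 follicular arrays and 0 of 4 luteal arrays, at least 1.17-fold lower in the luteal phase. This bound holds for the neqc values only: the log2 difference was -0.39 there and -0.09 with the authors' values.

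**Figure D2:**
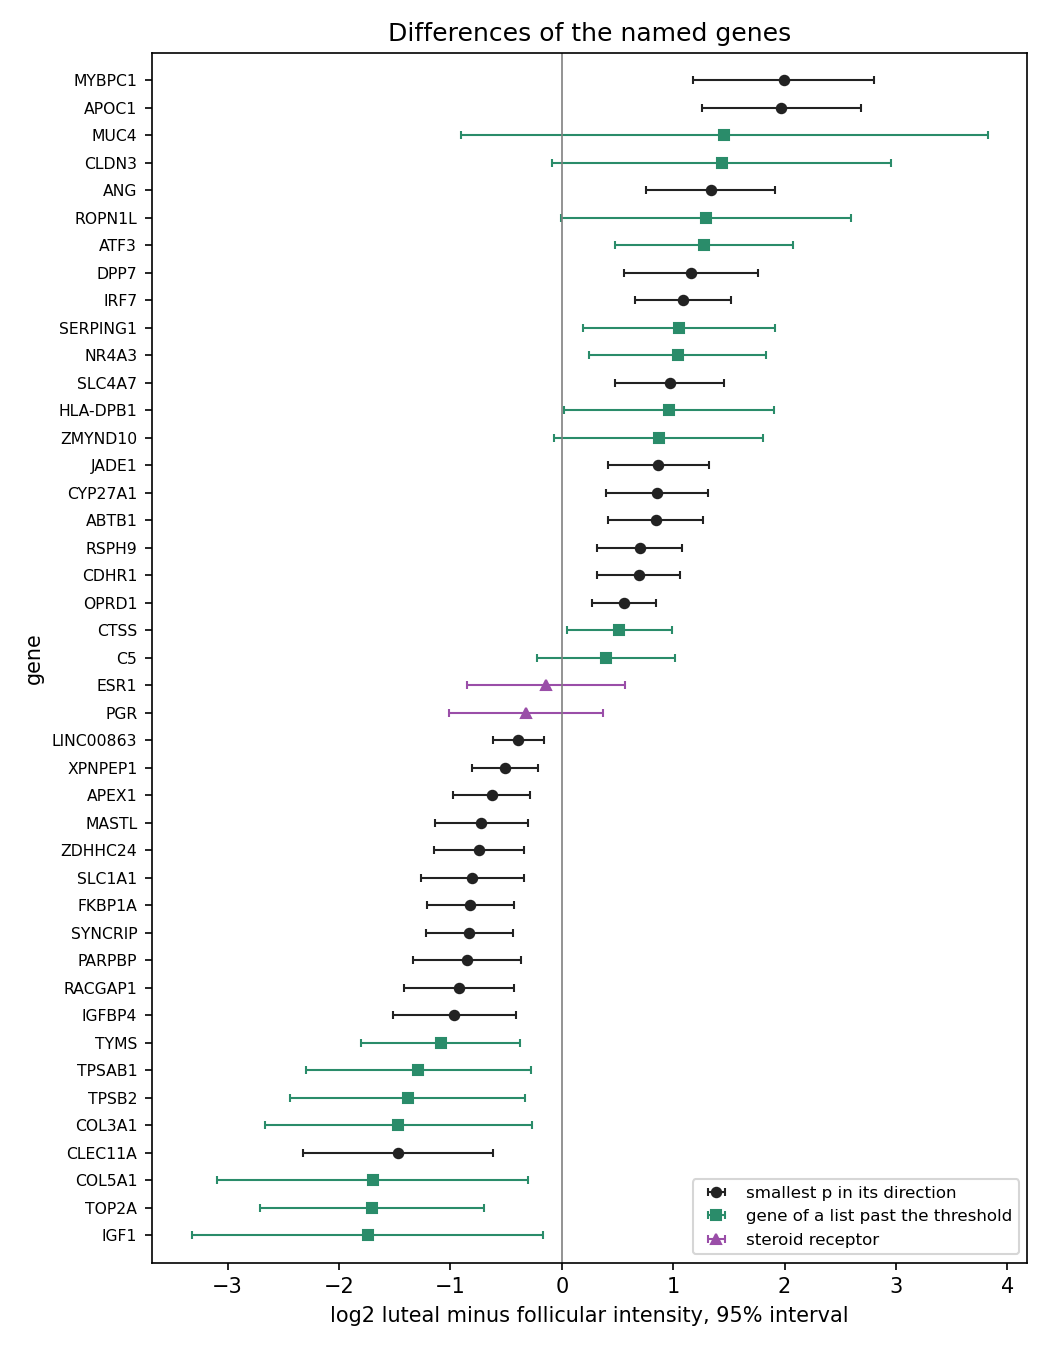
Luteal minus follicular difference in log2 intensity (horizontal axis) for each named gene (vertical axis), with 95% confidence intervals from limma that are not adjusted for the number of genes; black dots mark genes of smallest p in their direction, green squares genes of lists past the threshold and purple triangles steroid receptors. Differences run from -1.74 for IGF1 to 1.99 for MYBPC1, and the intervals of ESR1, PGR, ROPN1L, ZMYND10, C5, CLDN3 and MUC4 include 0.

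Smooth muscle and columnar epithelium genes varied more within the phases than between them. Smooth muscle genes averaged 9.001 ± 1.43 (SD, n = 8) in follicular and 8.35 ± 1.17 (SD, n = 4) in luteal arrays, and columnar epithelium genes 9.26 ± 1.85 (SD, n = 8) and 9.92 ± 0.83 (SD, n = 4). The follicular SD of columnar genes was 0.46 without follicular replicate 2 (n = 7). For mast cell genes the difference of -0.89 exceeded the follicular SD of 0.665 (n = 8) and not the luteal SD of 1.02 (n = 4). The first principal component, 36.6% of the variance, set follicular replicate 2 apart from all other arrays and did not differ between the phases (exact permutation p = 0.772).

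**Figure D3:**
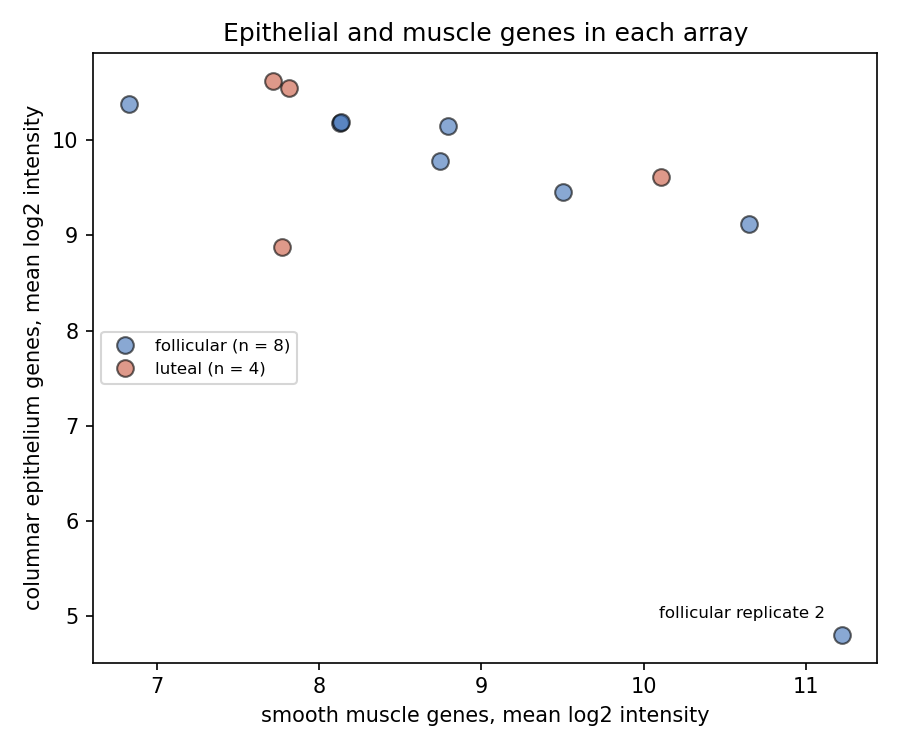
Mean log2 intensity of columnar epithelium genes (vertical axis) against smooth muscle genes (horizontal axis) in each array, follicular n = 8 in blue and luteal n = 4 in red; dots of 2 follicular arrays overlap. Follicular replicate 2 sits at 4.80 for epithelium and 11.2 for smooth muscle, and the other arrays lie at 8.87 or above for epithelium.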

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

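Values far from the rest of their phase were sought among the named genes, the lists and 2 array measures. Of 158 groups of values, 18 held such a value, where chance gives about 7.9 (1 in 20), and 8 of the 18 lay in follicular replicate 2. The tests of that array were chosen after the result had been seen.

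Follicular replicate 2 had the lowest value of its phase, far from the others, for the columnar epithelium list (4.80, next 9.11), complement (5.74, next 7.37), secretory-phase endometrium (5.42, next 6.86) and HIV receptors and restriction factors (6.89, next 7.56). The same held for CLDN3 (4.45, next 7.59), ESR1 (9.45, next 10.5), the number of probes detected (17706, next 20392) and the median unnormalized signal (93.6, next 101). A weak signal from all cell types alike would have lowered muscle genes before normalization too. Their unnormalized mean lay 1.56 above that of the other 7 follicular arrays on the log2 scale, more than the SD of 1.01 between those, which argues against such a signal as the whole source. The value still lay within their range, at 10.97 against a highest of 11.07. A weak signal as a part of the source stays open. Whether the tissue piece held little epithelium stays open: the columnar mean, at -11.0 SDs from those arrays, is the observation itself and no test of it. Fibroblast and stroma genes were not high, at 9.70 against 11.35 ± 0.92 in those arrays (SD, n = 7). How the piece was cut is not recorded, and no biological explanation within the follicular phase was tested.

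Squamous epithelium genes were far higher in follicular replicate 6 (11.7, next 7.55) than in the other follicular arrays, and in luteal replicate 3 (6.51, next 5.51) than in the other luteal arrays. Endothelial genes were lowest in follicular replicate 6 (5.86, next 6.63). Smooth muscle genes were highest in luteal replicate 1 (10.1, next 7.81).

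Among single genes, MYBPC1 was at 4.80 in luteal replicate 4 and at 7.03 or above in the other luteal arrays. OPRD1 was highest in follicular replicate 5 (4.98, next 4.59), DPP7 in follicular replicate 8 (9.39, next 8.34) and ZMYND10 in follicular replicate 6 (6.25, next 5.26). JADE1 was lowest in follicular replicate 3 (6.54, next 6.84). LINC00863 was highest among luteal arrays in replicate 1 (4.64, next 4.48), where no luteal array detected it.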

How the results depend on the processing

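The exact permutation of list means and the setting without discordant probes were chosen after the data had been seen. The slide block was not run, since no slide is named. A list was not tested with its own mean as the covariate, which leaves nothing to test. No cause was tested for the values below, except where stated. No gene was called in any setting except without luteal replicate 4, which called 1, MYBPC1 (adjusted p = 6.7e-05), so leaving out arrays gave 0 to 1. Among the luteal arrays, MYBPC1 was lowest in that one. Smallest adjusted p-values in the other settings ran from 0.0993 upwards.

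The count of 701 genes at an unadjusted p under 0.05 became 455 with detection at 0.01 in all 12 arrays, which tested 7773 genes, and 1170 with every probe tested, over 22445 features. It became 1489 with array weights and 1391 with the columnar covariate. Leaving out arrays gave 401 (without luteal replicate 4) to 1576 (without follicular replicate 2).

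The count of 9 lists became 4 with detection in all 12 arrays, 5 with array weights, 14 with the squamous covariate, 3 with the columnar covariate, and 0 with an estimated correlation or by exact permutation. By exact permutation a list could not pass the adjusted threshold alone. Leaving out arrays gave 5 (without luteal replicate 3 or 4) to 15 (without follicular replicate 6), with 6 without follicular replicate 2. The 9 lists kept their direction in all alternatives run. Proliferation (-0.77 to -0.22) and ciliated cells (0.41 to 1.26) stayed past the threshold in 26 of 27 alternatives each and immediate-early genes (0.37 to 0.77) in 27 of 28, losing it with the estimated correlation. With detection in all 12 arrays the proliferation, ciliated cell and columnar lists could not be tested. Fewer than 5 of their members were left there, so their counts do not cover that setting. Mast cells stayed past it in 25 of 28, MHC class II in 23 of 28, estrogen-induced genes in 22 of 28, complement in 20 of 28, columnar epithelium in 18 of 26 and stroma in 16 of 28. Within these counts, the looser threshold of 0.10 and robust eBayes, which camera does not use, could not lose a list. All alternatives but the estimated correlation kept the preset correlation of 0.01, at which other splits gave a median of 10 lists. The counts therefore do not set these lists apart from chance. Of lists outside the 9, some passed in alternatives: hypoxia response in 12 of 28 (among them the looser threshold of 0.10), smooth muscle in 5 of 27, mucins in 3 of 27, endothelium and secretory-phase endometrium in 2 of 28 each, epithelial junctions in 2 of 27, squamous epithelium in 2 of 26 and heat shock proteins in 1 of 28.

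Other scalings gave smaller differences, except for COL3A1 and ESR1 with normexp and the authors' values. With the authors' values these genes gave -1.474 and -0.141, against -1.466 and -0.139. With the authors' values 25 of the 43 named genes and 6 of the 9 lists had a difference more than 1.5 times smaller, with no background correction 24 genes and 5 lists, and with normexp 19 genes and 2 lists. APOC1 gave 1.05, 1.11 and 1.42 under these 3, against 1.97, and TOP2A -0.56, -0.61 and -0.93, against -1.70.

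A change of sign occurred 65 times in 16 lists, all of them outside those 9 and past the threshold in neither setting. Inflammatory genes gave -0.030 with no background correction, -0.018 with normexp, -0.033 with the authors' values, -0.011 with no filter, -0.0041 with the mean of probes, -0.27 with array weights, -0.31 with the smooth muscle covariate and -0.29 with the columnar one. Ribosomal proteins gave 0.011 with no background correction, 0.0014 with normexp, 0.014 with the authors' values and 0.088 with detection in all arrays. Epithelial junctions gave -0.041 with array weights, -0.18 with the smooth muscle covariate and -0.17 with the columnar one. With the squamous covariate, antimicrobial proteins gave 0.16, B and plasma cells 0.089, ion and water transport 0.076 and T cells 0.11. With every probe tested, B and plasma cells gave 0.00014, matrix remodelling 0.10 and T cells 0.0080. Monocytes and macrophages gave -0.016 with array weights, and interferon-stimulated genes -0.011 with the mean of probes and -0.0083 with the columnar covariate.

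Leaving out single arrays gave these ranges: antimicrobial proteins -0.56 to 0.18, B and plasma cells -0.17 to 0.15, endothelium -0.38 to 0.0010, epithelial junctions -0.13 to 0.44, heat shock proteins -0.019 to 0.44, HIV receptors and restriction factors -0.20 to 0.036, inflammatory genes -0.33 to 0.24, interferon-stimulated genes -0.027 to 0.14, ion and water transport -0.26 to 0.16, matrix remodelling -0.21 to 0.069, monocytes and macrophages -0.12 to 0.20, prostaglandin metabolism -0.17 to 0.018, ribosomal proteins -0.075 to 0.082, squamous epithelium -0.85 to 0.19, steroid receptors and coregulators -0.24 to 0.016, T cells -0.12 to 0.12, and among named genes ESR1 -0.34 to 0.059. In no other alternative did a named gene change sign. Signal over background limits dim genes such as LINC00863 and TOP2A, near the level of undetected probes in luteal tissue.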

Other observations

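Of the tests below, these were chosen only after their result had been seen: other splits for the count of called genes, the permutation of the proliferation list, the cholesterol list, the mitotic list without its members of smallest p, and for probes that disagree with a sister probe the tests of pairwise correlation and of phase. Further gene groups were tested because related genes stood among those of small p. None of the 24 genes named in the report for their small p is a member. Mitotic genes outside the proliferation list were lower in the luteal phase for 21 of 22 members, by -0.50 on average, with an adjusted p over the 4 added lists of 6.6e-12 in camera. MELK, a mitotic kinase, differed by -0.88 and NUSAP1, a spindle protein, by -1.16. The luteal mean of MELK was 4.246, below the 4.288 of an ATF3 probe detected on no array. The size of such differences may therefore depend on the background correction. The proliferation list went from -0.68 to -0.22 with the authors' values, and the added mitotic list was not tested on that scale. For the mitotic list the adjusted p was 0.113 with an estimated correlation. The exact permutation p of its mean was 0.0141, or 0.0566 adjusted over the 4 lists. Without the 3 members among the 200 genes of smallest p, the other 19 differed by -0.45, with an exact permutation p of 0.0283, or 0.113 adjusted. These mitotic genes serve the same process as the proliferation list and were measured on the same arrays. Their result is therefore no independent test of that list. Collagen assembly genes outside the stroma list were lower for 17 of 18 members, by -0.61, among them POSTN at -0.92. Cilia genes outside the ciliated cell list were higher for 13 of 14, by 0.57, among them CFAP45 at 0.93. Camera gave these 2 lists adjusted p-values of 4.0e-05 and 1.9e-04, but with an estimated correlation each had an adjusted p of 0.325 and in the exact permutation test p-values of 0.208 and 0.271. Whether collagen and cilia genes differ as classes stays open. A hypothesis that cholesterol and LXR target genes are higher as a class, taken from APOC1 and CYP27A1, stays open: 15 other genes differed by -0.024 on average (exact permutation p = 0.935). The genes named here were chosen after their values were seen.

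The lower level of proliferation genes was weighed against tissue composition and chance. With the smooth muscle mean as a covariate the list difference was -0.63, with the columnar mean -0.64 and with the squamous mean -0.69, against -0.68 without. The list stayed past the threshold in camera with each. The size kept with the smooth muscle mean argues against the share of that tissue as the whole source. The columnar mean mainly set follicular replicate 2 apart (4.80, other arrays 8.87 or above). The squamous mean did so for follicular replicate 6 (11.7, next 7.55). These 2 covariates could hardly test a share in the other arrays, so columnar and squamous epithelium stay open. Chance stays open: the exact permutation p was 0.0202 before and 0.687 after adjustment over the 34 lists. A list could not pass alone after that adjustment, so the adjusted value cannot decide. With an estimated correlation, camera gave the list an adjusted p of 0.697. The phase of the cycle therefore stays a hypothesis for this list, and the shares of stroma, mast cells, endothelium and leukocytes were not tested as its source.

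Other splits of the 12 arrays into 8 and 4 did not exclude chance for the count of genes at an unadjusted p under 0.05 or for the count of lists. For called genes the comparison says nothing, since each of the 100 splits has at least the 0 of the real split; the highest of the others gave 6. At an unadjusted p under 0.05, 27 of 100 splits gave at least the 701 genes of the real split, and the highest other gave 1867. Camera at its preset correlation called at least 9 lists in 67 of 100 splits, and 23 lists in the highest other, a split that put follicular replicate 2 among the 4.

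On these arrays 365 probes of 319 genes were bright, averaging 8 or more on the log2 scale, while another probe of the same gene was detected on no array. As a whole their correlation lay within that of matched probes, over the 11 arrays without follicular replicate 2. The median pairwise correlation was 0.022, above the median of the 1000 random sets (0.010) and below their highest (0.030). A part of them moved together more than the random sets did, since 0.470% of pairs correlated above 0.9, against at most 0.310% in those sets. Separate transcripts of co-expressed genes would correlate too, so this excess does not go against such transcripts, which stay open. Array quality also stays open. The mean of the set correlated with the number of probes detected at Pearson r = 0.529 (permutation p = 0.0828) and Spearman rho = 0.518 (permutation p = 0.0875), and at r = 0.073 (permutation p = 0.827, adjusted p = 0.827 over the 3) without the 2 arrays farthest from the median, where the 95% interval of r over 10 arrays, from -0.583 to 0.672, excludes neither sign. For phase, the highest follicular array lay 0.013 above the highest luteal array, within the luteal SD of 0.033, and the means were 9.33 and 9.35 (exact permutation p = 0.812), so phase cannot be told apart from no difference.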
